A study of Physcomitrium patens with 24 samples.

How the data were processed

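The study's 24 strand-specific PIP-seq libraries came from protonema of Physcomitrium patens crosslinked with formaldehyde, per the labels' protocols. Liquid cultures received ABA for 30 or 60 min, and the control received methanol, the solvent, per the labels' protocols. Each homogenate was divided into a protein-bound part, digested with RNase before proteinase K, and a structure-only part, treated with proteinase K before the RNase. Each part was again divided between RNaseONE (ssRNase) and RNase V1 (dsRNase). Short labels call one library type plusP, with a description that names a protein kinase treatment where the protocol names proteinase K, so which label is which state was not settled here and no result depends on it. The 2 replicates of each of the 12 groups are numbered in the labels, which do not say that they came from separate cultures. The dsRNase and ssRNase libraries of a replicate come from 1 divided sample, which fits of both RNases together did not take into account. All p-values therefore measure the spread between these samples, which may be technical.

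The submitters' processing notes name cutadapt 1.2.1 and TopHat2 2.0.10, and the genome build mm10, which is a mouse build. The lists use chromosomes 1 to 27 and scaffolds, which are not those of a mouse, so the build of the coordinates is not given in the sources used here. The peak caller is not described in the labels; the name of each deposited list contains CSAR, a false discovery rate of 5% and the word trimmed, and nothing further on these steps is given in the sources used here. Each deposited list holds chromosome, start, end, strand, a score and the names of the merged calls. The score is a value the authors deposited with no stated unit. It grew with the number of merged call sets (at 0 min its lowest value was 6.45 for sites of 1 set and 28.6 for sites of all 4), so it was used only to rank sites within a list. Call names give time, RNase, replicate and a running number, and each name type was taken as 1 call set, made from a protein-bound and a structure-only library. The running numbers of each set had no gaps, which leaves open whether calls were removed before numbering or from the end of a set. The deposited lists hold no read counts, so sequencing depth is unknown and no depth-based limit can be given.

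The reference table given for naming genes holds 27567 genes of an assembly (ASM5946719v1) with 26 chromosomes. It has no product names, and its build differs from that of the lists, so none of its coordinates or names were used. Planned results on location in transcripts, start and stop codons, named genes, gene lists and sequence could not be run for this reason and were not analysed here. Regions took the place of genes. Coordinates are 1-based and as in the lists.

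From the lists, site numbers, widths and covered lengths were counted, and sites of different times were called shared at an overlap of at least 1 nt on the same strand, with 95% Wilson intervals. Placement within a site's own region (regions of at least 1000 nt, 100 draws) replaced the planned placement within exons. Overlapping sites of the 3 lists on a strand were joined into loci, and sites less than 500 nt apart into regions. A locus was gained when both replicates of the later time and neither of the earlier had a call. Agreement of 2 call sets was the share of loci called in both among those called in either, tested by exact permutation over the 15 pairings of 6 sets. Numbers of calls were compared by exact two-sided permutation tests.

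For regions, a prior of 0.5 calls was added to the number of called loci per dsRNase set, and the result was scaled per call set and per strand. Sets without a call therefore got unequal values. Log2 values were fitted with limma 3.58.1 (R 4.3.3) with a mean trend, all 3 times in one fit and Benjamini-Hochberg adjustment at 0.05. Regions with a mean of at least 2 calls were tested (4502). A fold against a time with no call was taken against a floor of 3 calls per set. Fitted log2 changes understate changes of regions with few calls. The choice of comparisons and overlap rules, and of the settings to vary among them, was made before the data were examined. The region test was not: the use of call sets, the 500 nt gap, the minimum of 2 calls, the dsRNase sets and the scaling per strand were all chosen after the data were examined, and counts under several of these settings had been seen when scaling per strand was preferred. The reason for that choice was that replicates of 1 time differed in their share of calls on the plus strand. The test was tried on simulated calls drawn binomially from each region's loci, with 200 regions changed. For 60 against 0 min it recovered 0% of tested changed regions at 2-fold, 12.3% at 4-fold and 41.7% at 8-fold, among about 4500 regions, with 0 wrong calls. With as few regions changed as there, most changes of 4-fold or less would be missed. In the data 34.7% of regions had an unadjusted limma p under 0.05 for 60 against 0 min. That makes the adjusted threshold more lenient than in the simulation, so recovery in the data is not known. An earlier simulation, with overdispersed (negative binomial) calls, recovered almost none of the changed regions and was replaced after that was seen. In the version used the residual SD was 0.372 at 2-fold against 0.344 in the data.

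Named regions follow the rule fixed for genes, applied to regions after the files were seen. It takes the 6 largest gains and 6 largest losses of covered length per comparison and the 5 regions with most covered length at 0 min. A second rule, the 4 largest fitted changes each way among those past the test, was added after the values were seen. Regions were called matching copies when at least 2 successive combinations of site width, gap and width were identical, and these made up at least 30% of those of the smaller region. That gave 273 pairs, against 7 after shuffling widths and gaps within regions. Copies whose sites differ in width would escape this match.

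Settings chosen for variation before the data were examined were the higher-scoring part of each list, merging within 10 nt, a minimum width of 20 nt, a 50% overlap, ignoring the strand, thinning to equal size, omission of the 1% densest regions, stricter size rules, omission of each replicate and a replicate block. Those added after seeing the data were other scalings, minimum calls, priors, region gaps and RNases, and fits of each comparison on its own 4 sets. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.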

Results

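Protein interaction profile sequencing (PIP-seq) maps stretches of RNA that bound proteins shield from nucleases. It was applied to protonema, the filamentous juvenile tissue of the moss Physcomitrium patens, collected after 0, 30 or 60 min of abscisic acid (ABA), the plant hormone of drought and osmotic stress. The labels give 24 libraries in 12 groups of 2 replicates. A group is a time, an RNase and a protein state. The RNase was single-strand-specific (RNaseONE, here ssRNase) or acted on paired RNA (RNase V1, here dsRNase). In the protein-bound libraries crosslinked proteins stayed on the RNA during digestion, and in the structure-only libraries they had been removed beforehand. The ABA dose is 10 µM in the design text and 10 mM in the treatment protocol, and the 2 sources were not reconciled here. The labels list no group without ABA at 30 or 60 min. An effect of ABA therefore cannot be told apart from elapsed time or from anything else particular to the 0-min samples. The files analysed were 3 lists of protein-protected sites, 1 per time. The site names show that each list merged calls from 4 call sets, namely dsRNase and ssRNase in replicates 1 and 2, so 12 call sets could be compared. The lists carry no read counts and no RNA levels. The depth of each library is therefore unknown, and a region with more sites may hold more RNA or more bound protein.

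The question here was how many protected sites were found at each ABA time. The list held 52248 sites at 0 min, 47781 at 30 min and 47102 at 60 min. Sites were wider at 30 min, with a median of 42 nt against 35 nt at 0 min and 39 nt at 60 min. The covered length was 2564.86 kb at 0 min, 2878.97 kb at 30 min and 2514.42 kb at 60 min. The order of the site numbers of 0 and 30 min depended on which replicate number was kept. Without replicate 1 of both RNases at each time they were 41245 and 30786, and without replicate 2 they were 37825 and 40991. The 27 chromosomes held 99.3% of the sites at 0 min and 99.4% at 30 and 60 min, and scaffolds held the rest. DsRNase sets held 40616.5 ± 4294 calls at 0 min, 35532.5 ± 8145 at 30 min and 37549 ± 1790 at 60 min (SD, n = 2). Exact two-sided permutation tests gave p = 0.667 for 30 against 0 min, p = 0.667 for 60 against 0 min and p = 1 for 60 against 30 min (n = 2 per time), and the smallest p this design allows is 0.333.

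The 2 RNases gave very different numbers of calls. At 0 min the ssRNase sets held 8955.5 ± 927 calls, at 30 min 14140.5 ± 5098 and at 60 min 7660 ± 339 (SD, n = 2). The 30-min mean rests on replicates of 10536 and 17745 calls, both above the 8300 to 9611 calls at 0 min and the 7420 to 7900 at 60 min. Exact permutation tests reached the smallest possible p of 0.333 in each of the 3 comparisons (two-sided, n = 2 per time), so no difference could pass a threshold. Sites with ssRNase support made up 21.3% of the list at 0 min, 33.2% at 30 min and 19.2% at 60 min. Most of them also had dsRNase support, with 79.8% at 0 min, 80.3% at 30 min and 81.0% at 60 min. Of the sites with dsRNase support, 50.5%, 47.5% and 53.7% were called in both replicates at 0, 30 and 60 min. For ssRNase these shares were 37.1%, 40.6% and 39.7%.

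**Figure D1:**
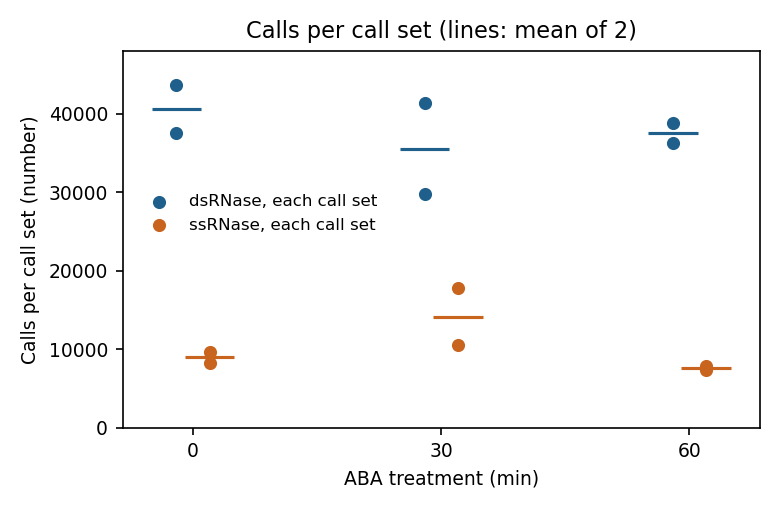
Calls per call set (y axis, number) against the time of ABA treatment (x axis, min). Points are single call sets, lines are means of 2 replicates, and the ssRNase points at 30 min (10536 and 17745) lie above those at the other times.

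Positions were compared between times to ask how much of the protected landscape was shared. Of the 0-min sites, 63.9% (95% Wilson interval 63.5 to 64.3%) were overlapped by at least 1 nt on the same strand by a 30-min site, and 57.7% (57.3 to 58.2%) by a 60-min site. Of the 30-min sites, 69.7% (69.3 to 70.1%) were overlapped at 60 min, and 76.1% (75.7 to 76.5%) of the 60-min sites at 30 min. At 0 min 66.2% of the 30-min sites and 65.6% of the 60-min sites were overlapped, less than between the treated times. In regions of at least 1000 nt, overlap was 1.54 to 1.60 times that of sites placed at random within their own region (100 placements). As a ratio to such placement the treated times shared no more with each other (1.55-fold for 30-min sites and 1.56-fold for 60-min sites) than with 0 min (1.57-fold and 1.60-fold). A ratio has less room where placed overlap is high, so this decides nothing. Between the treated times overlap was 76.9% and 81.8%, against 49.6% and 52.5% when placed. With 0 min it was 66.6% and 65.3%, against 42.5% and 40.7%, a smaller excess in percentage points. Sites with wide support recurred most. Of the 0-min sites called in all 4 sets, 95.1% were overlapped at 60 min, against 36.0% of those called in 1 set. The former were also wider, with a median of 92 nt against 28 nt. Wider sites are overlapped more readily by the 1 nt rule, so support and width were not separated. Sites of the 3 lists fell into 71136 loci, of which 23101 (32.5%) had a site at all 3 times. A further 14423 loci had a site at 0 min alone, 7129 at 30 min alone and 6771 at 60 min alone, and 8499 had a site at 30 and 60 min but not at 0 min. Intervals cover counting error alone.

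Call sets were then compared with each other, since they are the unit that is replicated. DsRNase sets of the same time shared 50.96% ± 3.29 of the loci called in either (SD over 3 pairs), and sets of different times shared 41.6% ± 4.88 (SD over 12 pairs). By times, sets of 0 and 30 min shared 39.6%, sets of 0 and 60 min 37.5%, and sets of 30 and 60 min 47.6%. The replicates of 0, 30 and 60 min shared 50.8%, 47.8% and 54.3%, so those of 30 min agreed about as much as sets of 30 and 60 min. Of the 15 ways to pair the 6 dsRNase sets, the true replicate pairs gave the highest mean (exact one-sided permutation p = 0.0667, the smallest possible). SsRNase sets shared 39.98% ± 2.11 within times and 33.3% ± 3.47 between times, with the same exact p of 0.0667. Neither test could reach 0.05.

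**Figure D2:**
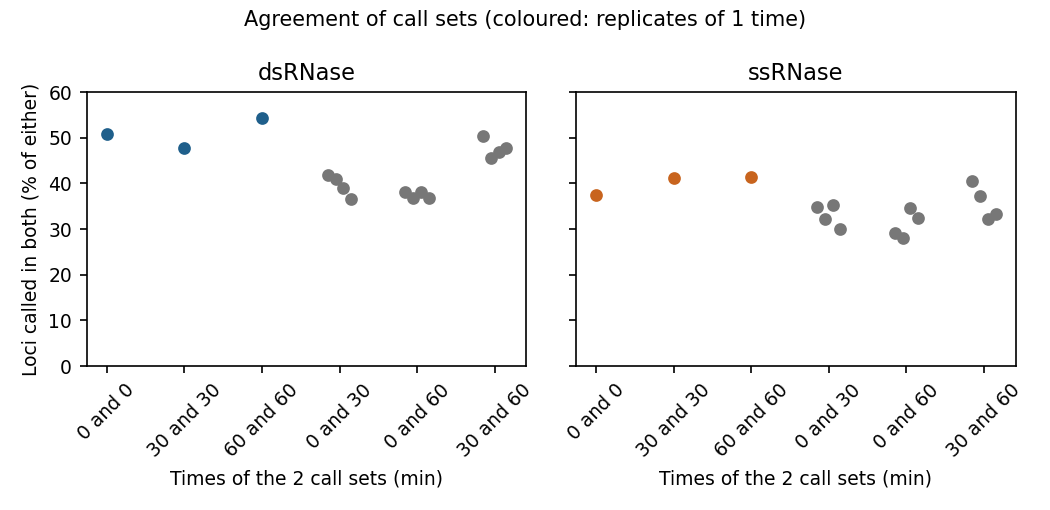
Share of loci called in both of 2 call sets, as percent of loci called in either (y axis), for each pair of call sets grouped by their times (x axis, min). Coloured points are replicates of 1 time and grey points are sets of different times; for dsRNase, pairs of 30 and 60 min (mean 47.6%) lie above pairs of 0 and 60 min (mean 37.5%).

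Counting loci called in both dsRNase replicates of a time and in neither of the other, 4695 loci were gained and 4539 lost from 0 to 30 min. From 0 to 60 min 6470 were gained and 5502 lost, and from 30 to 60 min 2820 were gained and 2287 lost. With 1 set left out, so that 1 call rather than 2 decides, these counts moved up, to 5950 to 12793 gained and 6479 to 13434 lost by 30 min, 7687 to 11864 and 7577 to 14085 by 60 min, and 4248 to 7704 and 3697 to 10614 between 30 and 60 min. Losses by 30 and by 60 min then outnumbered gains without either 0-min set, as did losses by 30 min without replicate 1 of 30 min and losses between 30 and 60 min without replicate 2 of 30 min. When the same 4 sets were split the other ways, which mix the times, the totals were at most 3147, 2446 and 4100 loci, against true totals of 9234, 11972 and 5107. The ssRNase calls were not used to call a locus gained or lost. From the earlier to the later time, loci with an ssRNase call went from 101 to 1719 of those gained by 30 min, from 87 to 1141 of those gained by 60 min and from 193 to 152 of those gained between 30 and 60 min. Among lost loci they went from 491 to 363 by 30 min, from 733 to 173 by 60 min and from 551 to 135 between 30 and 60 min. The larger number of ssRNase calls at 30 min (a mean of 14140.5 against 8955.5 at 0 min and 7660 at 60 min) enters these counts. In the ssRNase sets themselves 1962 loci were gained and 381 lost by 30 min, 789 gained and 1039 lost by 60 min, and 124 gained and 1809 lost between 30 and 60 min. With 3 splits per comparison, no p under 0.05 is possible here.

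Sites of any time less than 500 nt apart on a strand were joined into 21400 regions, which stand in for genes because no annotation of the files' build was used here. A site was present in 16956 regions at 0 min, 14424 at 30 min and 13072 at 60 min, and 8913 regions (41.6%) had a site at all 3 times. Regions seen at a single time numbered 4437 at 0 min, 1613 at 30 min and 1211 at 60 min. By a rule of size alone (covered length at least 2-fold and 50 nt apart), 2096 regions had more and 1942 less covered sequence at 30 than at 0 min, 2030 more and 2896 less at 60 than at 0 min, and 876 more and 1786 less at 60 than at 30 min. The most covered region at 0 min lay on chromosome 21 (2831244 to 2839989, plus strand), with 7169 nt covered at 0 min, 7084 nt at 30 min and 6779 nt at 60 min. The next ones lay on chromosome 8 (11648692 to 11659620, minus strand, 4881 nt), chromosome 14 (5634046 to 5642686, plus strand, 4748 nt) and chromosome 10 (9450502 to 9456674, plus strand, 4739 nt, and 9467095 to 9473225, minus strand, 4708 nt). The chromosome 10 regions matched each other in their pattern of site widths and gaps, so reads could be shared between them.

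At 30 min of ABA most of the regions past the test were gains, which the minimum of calls over all 3 times favours. Among 4502 regions tested, 724 had more dsRNase calls at 30 than at 0 min and 158 had fewer, by limma on scaled log2 call numbers with Benjamini-Hochberg adjustment. Of the regions with more calls, 322 (44.5%) had no call in any of the 4 sets at 0 min. On chromosome 10 a region of 6493 nt (5028443 to 5034935, plus strand) had 0 calls in both dsRNase sets at 0 min and 33 and 37 calls at 30 min, at least 11.7-fold more than a floor of 3 calls per set (limma adjusted p = 9.5e-08, higher in 2 of 2 sets). Its covered length went from 0 to 3409 nt, and ssRNase calls from 0 in both sets to 16 and 24. A region on chromosome 2 (18160365 to 18166065, minus strand) likewise went from 0 calls to 31 and 35, at least 11-fold, with covered length rising from 0 to 2831 nt (adjusted p = 8.24e-08). Gains from few calls were seen on chromosome 22 (14155141 to 14164136, minus strand), from 0 and 1 to 32 and 42 calls, and on chromosome 10 (4555970 to 4560018, plus strand), from 1 and 0 to 19 and 21. On chromosome 15 (10339194 to 10342941, plus strand) calls rose from 2 and 0 to 16 and 16. A region on chromosome 5 (13944975 to 13951321, plus strand) rose by 3.67 ± 0.28 on the log2 scale (SE), from 3 and 2 calls to 38 and 38 (adjusted p = 8.93e-07).

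Losses past the test at 30 min were fewer and mostly partial. Of the 158 regions with fewer calls, 6 had no call left in any 30-min set. A region empty at both treated times was tested only if its 0-min calls alone reached the minimum mean. Complete losses were thus tested less readily than gains from no call. On chromosome 15 a minus-strand region (15962640 to 15966015) fell by 1.85 ± 0.38 on the log2 scale, from 17 and 20 calls to 4 and 3 (limma adjusted p = 0.00297). A plus-strand region 66.8 kb away (16032806 to 16036182) fell by 1.80 ± 0.36, from 19 and 17 calls to 6 and 4 (adjusted p = 0.0027). Their spans, 3376 and 3377 nt, are nearly equal, but their site patterns did not match, so whether they are copies that share reads was not settled. The call at 15962640 did not pass without replicate 1 of 0 min, and that at 16032806 without either replicate of 0 min. Another region on chromosome 15 (7733642 to 7737363, plus strand) fell from 23 and 18 calls to 6 and 6 (adjusted p = 0.00476), and a region on chromosome 7 (1153709 to 1158882, minus strand) from 31 and 30 to 9 and 10 (adjusted p = 0.0407), a call that did not pass without replicate 1 of 0 min or of 30 min, without scaling, at a minimum mean of 1 call or with a prior of 0.25 calls. Without scaling, the calls at 7733642 for 30 min, at 1153709 for 60 min and at 10339194 for both times did not pass either. On chromosome 26, 2 regions (3750692 to 3753381 and 3772617 to 3775306, minus strand) whose site patterns match each other and a further region went from 2478 and 2491 nt covered to 1488 nt each and did not pass the test (log2 -0.60 ± 0.29, adjusted p = 0.211). Both passed without scaling (log2 -0.999, adjusted p = 0.00346) and in the higher-scoring part of the lists, and after thinning the change at 3750692 was 0.015. The number of losses was sensitive to single call sets, with 50 when replicate 1 of 0 min was left out, 83 without replicate 2 of 0 min, 274 without replicate 1 of 30 min, and 248 and 240 without replicates 1 and 2 of 60 min, and 270 when the comparison was fitted on its own 4 sets. Scaling by all calls in place of each strand gave 141 losses, of which 21.3% lay on the plus strand against 48.1% in the counts above.

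After 60 min of ABA the gains were as broad, and losses were more frequent than at 30 min. Of the 4502 regions, 801 had more dsRNase calls at 60 than at 0 min and 356 had fewer. No call in any 0-min set was found for 347 of the gained regions (43.3%), and no call in any 60-min set for 56 of the lost regions (15.7%). A chromosome 27 region of 7805 nt (4598794 to 4606598, plus strand) had 0 calls at 0 min, 14 and 11 at 30 min and 44 and 43 at 60 min, at least 14.5-fold above the floor (limma adjusted p = 5.83e-08). On chromosome 26 (2365188 to 2373669, plus strand) calls went from 0 to 41 and 39 at 30 min and 40 and 36 at 60 min, at least 12.7-fold at 60 min. On chromosome 4 (15610510 to 15614450, plus strand) they went from 0 to 19 and 18 at 60 min, at least 6.17-fold, with ssRNase calls of 10 and 10 from none. The chromosome 10 regions named for 30 min stayed high, with 35 and 32 calls and with 20 and 23 calls at 60 min, as did the chromosome 15 region at 10339194, with 15 and 18.

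Among the losses at 60 min, the chromosome 15 pair at 15962640 and 16032806 had no call left in any of the 4 sets, at least 6.17-fold and 6-fold lower than at 0 min. A chromosome 26 region (5134686 to 5140324, minus strand) fell by 2.77 ± 0.31 on the log2 scale, from 25 and 27 calls to 4 and 2 (limma adjusted p = 1.82e-05). Its ssRNase calls fell by 3.26 on the log2 scale (adjusted p = 0.00102). The chromosome 15 region at 7733642 fell further, to 3 and 1 calls (log2 -3.12 ± 0.37, adjusted p = 3.43e-05), and the chromosome 7 region at 1153709 to 9 and 3 (log2 -2.21 ± 0.39, adjusted p = 0.000696). On chromosome 21 (6479421 to 6481972, minus strand) calls fell from 15 and 16 to 1 and 2, in a region with a matching copy nearby. Outside the rule, and chosen after its values were seen, a chromosome 1 region (26674254 to 26677572, plus strand) went from 14 and 13 calls to 7 and 9 and then to 0, at least 4.5-fold lower at 60 min. The chromosome 14 region at 5634046 lost the most covered sequence, from 4748 to 2833 nt, and its calls did not pass the test (log2 -0.66 ± 0.26, adjusted p = 0.0848), though they passed when that comparison was fitted on its own 4 sets, without scaling, with both RNases, with a prior of 1 call, with a 200 nt gap, in the higher-scoring part of the lists and without either 30-min set. The number of losses was 184 without replicate 1 of 0 min.

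**Figure D3:**
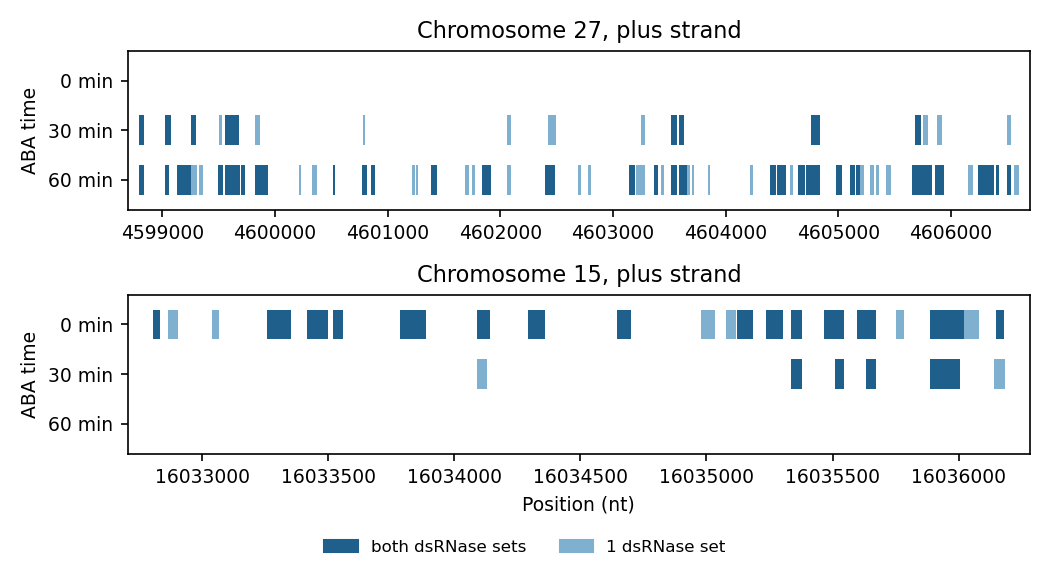
Protected sites along a region gained on chromosome 27 and a region lost on chromosome 15 (x axis, position in nt), 1 row per ABA time (y axis), drawn to scale. Dark bars are sites called in both dsRNase replicates and light bars in 1 of them; the first region has no site at 0 min and the second has none at 60 min.

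Regions past the test at 30 min were compared with those at 60 min. Of the regions with more calls, 668 passed at both times, 56 at 30 min alone and 133 at 60 min alone. Of those with fewer calls, 71 passed at both times, 87 at 30 min alone and 285 at 60 min alone. Independent lists would share 128.8 gains and 12.5 losses. Simulated unchanged groups against the same 0-min sets, with lists of the same sizes taken by rank, shared 291 to 333 gains and 40 to 68 losses in 20 simulations, a comparison chosen after the overlap was seen, so the 71 shared losses lie little above it. Passing at 1 time alone does not show a difference between the times: of the gains at 30 or 60 min alone 2 and 13 also passed between 30 and 60 min, and of the losses 3 and 49. With 1 of the 0-min sets for each comparison, a division also chosen afterwards, 531 and 513 gains were shared where independent lists would share 95.7 and 97.8, and 22 and 15 losses where they would share 3.08 and 2.77. Each comparison then rests on a single control set, and part of the overlap with both sets in each may come from the shared controls. No region passed in opposite directions.

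**Figure D4:**
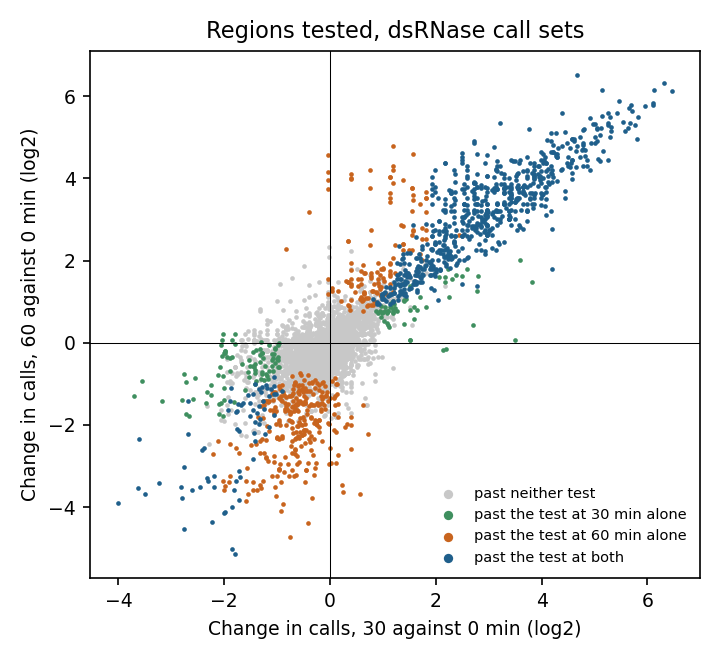
Fitted change in dsRNase calls of each of the 4502 tested regions at 30 min (x axis) and at 60 min (y axis), each against 0 min, on the log2 scale. Blue points passed the test at both times, and 668 of these lie in the upper right and 71 in the lower left.

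Between 30 and 60 min fewer regions passed the test than in either comparison with 0 min. Of the 4502, 23 had more calls at 60 than at 30 min and 54 had fewer, and 579 (12.9%) had an unadjusted p under 0.05. For 60 against 0 min the same test recovered 0% of simulated 2-fold and 12.3% of 4-fold changes, so the rest of the regions cannot be called unchanged. The chromosome 27 region at 4598794 rose by 1.87 ± 0.30 on the log2 scale (limma adjusted p = 0.0102), and a chromosome 16 region (9585699 to 9588467, minus strand) rose from 3 and 3 calls to 17 and 17 (adjusted p = 0.0214). A chromosome 21 region (6200696 to 6202425, minus strand) rose from 2 and 2 to 12 and 13 (adjusted p = 0.0348). The chromosome 17 region at 5180833 (to 5184883, minus strand), with 15 and 11 calls at 30 min and 31 and 29 at 60 min, did not pass (log2 1.00 ± 0.32, adjusted p = 0.151), though it passed in a fit of these 4 sets alone and in the higher-scoring part of the lists. Falls were seen in 2 regions on chromosome 20, on the plus strand (15098117 to 15100726) from 17 and 14 calls to 6 and 4 (adjusted p = 0.0192), and on the minus strand (15073149 to 15075764) from 11 and 12 to 5 and 3 (adjusted p = 0.0235). Their spans, 2610 and 2616 nt, are nearly equal, but their site patterns did not match. Whether these 2 are copies that share reads was not settled. Other losses named by the rule did not pass, on chromosomes 14 (5634046, limma adjusted p = 0.504), 12 (14137390, 0.392), 8 (11648692, 0.954) and 4 (16422654, 0.314). Nor did gains on chromosomes 2 (12667537, 0.369) and 19 (1527117, 0.0934). None of the 5 calls that passed held throughout. Those on chromosomes 16, 20 and 21 did not pass after thinning or with both RNases together, and both on chromosome 20 did not pass without scaling. With a prior of 0.25 calls those on chromosomes 16 and 21 and at 15073149 did not pass. The region at 15073149 also did not pass with the strand ignored, with scaling by all calls, at a minimum mean of 1 call or without replicate 2 of 30 min. Without replicate 2 of 60 min none of the 5 passed, and further calls were lost by those on chromosomes 16 and 21 without replicate 1 of 60 min and by that on chromosome 21 without replicate 1 of 30 min. Chosen after their values were seen, regions on chromosome 2 (8264540 to 8266071, minus strand) and chromosome 20 (3868747 to 3870679, plus strand) went from 9 and 7 calls each at 30 min to 0 at 60 min. The chromosome 2 region has a matching copy on the plus strand (8273368 to 8274520), which went from 9 and 6 calls to 0, so reads could be shared between them. The numbers of regions past the test between 30 and 60 min moved with single sets. Gains numbered 68 and 64 without replicates 1 and 2 of 0 min, 127 and 37 without those of 30 min, and 13 and 14 without those of 60 min, and losses 82, 90, 67, 52, 150 and 82 in the same order; without scaling there were 25 of each, and in a fit of these 4 sets alone 103 gains and 94 losses.

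The ssRNase calls took no part in the region test. Of the 801 regions gained at 60 min, 514 had more ssRNase calls at 60 than at 0 min, 21 had fewer and 266 were tied, but most had no ssRNase call at 0 min and could not fall. Of the 136 that had one, 99 had more and 21 fewer, where of 2208 such regions past no region test 297 had more and 1532 fewer. Of the 281 lost regions with an ssRNase call at 0 min, 267 had fewer and 5 had more. At 30 min, when the ssRNase sets held more calls overall (14140.5 against 8955.5), 115 of 124 gained regions with an ssRNase call at 0 min had more and 4 fewer, where of the regions past no test 1089 had more and 598 fewer. Of the 158 regions lost at 30 min 78 had fewer ssRNase calls, 37 had more and 43 were tied. From 30 to 60 min 10 of the 23 gained regions had more, 4 fewer and 9 were tied, and of the 54 lost 39 had fewer and none more, as 2041 of 3201 regions past no test had fewer too. Tested in the ssRNase sets alone (1195 regions), 151 regions had more and 7 fewer calls at 30 min, 191 more and 44 fewer at 60 min, and 0 more and 2 fewer at 60 against 30 min by limma, where 150 regions had an unadjusted p under 0.05. RNase-specific differences are given in the closing part.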

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

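All tests of this part except those of near-identical copies and of RNA level were chosen after the result they bear on had been seen. Thinning to equal size had been fixed beforehand as a setting to vary, though not as a test of this gain.

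The RNases differed in some regions when the difference itself was tested (limma, RNase by time interaction, 1154 regions). The fit took the dsRNase and ssRNase sets of a replicate as independent, though they come from 1 divided sample. The change differed in 2 regions for 30 against 0 min, in 27 for 60 against 0 min and in 1 for 60 against 30 min. Of the 27, 14 changed more upward with ssRNase and 13 more upward with dsRNase. In all 13 of the latter and 11 of the 14 former, 1 RNase or both had no call at 0 or at 60 min, so these interaction values depend on the prior. With a prior of 0.25 calls 43 regions differed for 60 against 0 min, 26 of the 27 among them, and with a prior of 1 call 21 did, 14 of the 27 among them. With these 2 priors 7 and 38 regions differed for 30 against 0 min, and 6 and 0 for 60 against 30 min. Examples with calls in all 4 sets at 0 min are a minus-strand and a plus-strand region on chromosome 20, where dsRNase calls at 15073149 went from 19 and 18 at 0 min to 5 and 3 at 60 min while ssRNase calls went from 2 and 2 to 3 and 4 (interaction log2 2.74, adjusted p = 0.0301), and at 15098117 from 18 and 16 to 6 and 4 while ssRNase calls went from 2 and 1 to 2 and 3 (2.69, adjusted p = 0.0301). In the other direction, on chromosome 16 (5299779 to 5303633, plus strand) ssRNase calls went from 13 and 13 to 0 and 0 and dsRNase calls from 22 and 21 to 4 and 7. This last difference rests on the empty ssRNase sets and did not pass with a prior of 1 call (adjusted p = 0.144), while both on chromosome 20 passed with either prior. The 2 chromosome 20 regions have nearly equal spans, 2616 and 2610 nt, though their site patterns did not match. Whether they are copies that share reads was not settled, so they may not be 2 separate examples.

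The gain of sites in 801 regions at 60 min was weighed against technical explanations. None of these tests separates ABA from elapsed time, because the 0-min samples were the only ones without ABA. A larger number of calls at 60 min is argued against, since the 60-min dsRNase sets held fewer calls on average than the 0-min sets and 621 regions still passed when all sets were thinned to one size. Strand balance is argued against for these gains, since with scaling by all calls, which leaves any imbalance in, 53.2% of them lay on the plus strand against 53.5% of the regions tested. It is not argued against for the losses at 30 min, of which 21.3% lay on the plus strand with that scaling. Reads shared by near-identical copies could account for few, as 2.75% of the gained regions had a matching copy, a figure that misses copies with unequal site widths. A higher RNA level and more bound protein cannot be told apart, because the lists hold no RNA level; 43.3% of the gained regions had no call in any set at 0 min, which either would give. With 3 splits of 4 sets, too few for a share under 0.05, the true split was the 1 split with as many regions, 1306 for 60 against 0 min against at most 0 otherwise, and likewise 998 against 0 for 30 against 0 min. The other splits mix the times, so a difference between times enters their error and little can pass. Of 4502 regions, 14 and 25 had an unadjusted limma p under 0.05 in them for 60 min, and 9 and 49 for 30 min. Their 0 is thus no rate of false calls. All splits were fitted on the 4 sets of a comparison alone. The true split then gave 854 gains and 452 losses at 60 min and 728 and 270 at 30 min, where the fit of all times gave 801 and 356, and 724 and 158. For 60 against 30 min the same fit gave 197 regions, 103 of them gains, against 23 gains and 54 losses in the fit of all times.

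The share of calls on the plus strand was uneven between call sets, from 46.3% in dsRNase replicate 2 of 0 min to 60.3% in ssRNase replicate 1 of 0 min. ABA time as the whole cause is argued against, since the largest gap between dsRNase replicates of 1 time, 9.42 percentage points, was 1.41 times the largest gap between time means. A strand-specific yield of single libraries stays open: sites called in 1 dsRNase set lay 2.69 times as far from an even share as sites called in both replicates (9.25 against 3.45 percentage points), but sites of all 4 sets lay farther from it than the latter (5.63 percentage points), which a yield of single dsRNase libraries alone would not give. At 0 min the single-set sites of replicate 1 were 66.7% on the plus strand and those of replicate 2 34.6%. What stays open is the 56.8% plus-strand share of the 30-min sites called in both dsRNase replicates (95% Wilson interval 56.1 to 57.5%), against 51.1% at 0 min, which a time effect could give. In sites of all 4 sets the shares were closer, 58.8% at 30 min (57.4 to 60.2%) and 56.3% at 0 min (54.5 to 58.0%).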

How the results depend on the processing

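In the limma test of call numbers, gained regions outnumbered lost ones at 30 and at 60 min against 0 min under every setting run, by varying amounts. Every setting kept a minimum mean of calls over all times, which favours gains over complete losses. The same direction under all settings therefore does not show that gains were more frequent than losses. The size rule on covered length gave more losses than gains at 60 against 0 min (2030 more and 2896 less) and nearly equal numbers at 30 min (2096 and 1942), while its stricter form with a 4-fold change gave more gains at both times (1044 and 773 at 60 min, 952 and 338 at 30 min). For regions the scalings, minimum calls, priors, gaps, RNases and fits on 4 sets, and for loci, call sets and regions the filters on score, width and density, were chosen after seeing the data, as were the test of regions itself and the thinning of loci; the others were chosen before. Of 317 alternative values of the 40 summary results, 185 stayed within their limits. For 54 named changes, 1056 of 1146 alternative values kept direction and side of the threshold, 56 lost the call, 24 gained one and 10 reversed. Read depth is unknown, so its effect on any of these could not be examined. The settings meant for location in transcripts, codon density, gene lists and hexamers were not run.

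In the order gains and losses for 30 against 0, 60 against 0 and 60 against 30 min, limma called 724 and 158, 801 and 356, 23 and 54 regions. The counts were 475 and 161, 575 and 301, 25 and 25 without scaling, 689 and 141, 780 and 305, 17 and 34 with scaling by all calls, 455 and 101, 474 and 207, 22 and 63 at a mean of 4 calls, 891 and 215, 1091 and 583, 23 and 38 at 1 call, 749 and 224, 852 and 431, 76 and 121 with a prior of 1 call and 685 and 102, 757 and 297, 4 and 33 with 0.25. They were 461 and 87, 501 and 224, 4 and 18 with both RNases, 151 and 7, 191 and 44, 0 and 2 with ssRNase alone (fewer regions tested), 693 and 93, 761 and 237, 11 and 42 and 730 and 203, 819 and 429, 37 and 65 with gaps of 200 and 1000 nt, 689 and 141, 776 and 306, 17 and 34 with the strand ignored and 561 and 61, 621 and 184, 7 and 18 after thinning. With each comparison fitted on its own 4 sets they were 728 and 270, 854 and 452, 103 and 94. The higher-scoring part of each list gave 1098 and 837, 1310 and 1042, 974 and 1040. The score sums over call sets, so that part keeps mostly sites of several sets, replicates agree by construction and these calls are too many. Apart from this and the smaller number of regions tested, the cause was not tested.

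Leaving out 1 set at a time, with the lone set assumed to vary like the others, gave 648 to 734, 50 to 274, 721 to 851, 184 to 448, 13 to 127, 52 to 150 regions in the same order. With a replicate block the counts were 718 and 170, 811 and 377, 20 and 61. Deviations of same-numbered dsRNase sets correlated at -0.0613, -0.0271 and 0.183 between 0 and 30, 0 and 60, and 30 and 60 min, so the numbers were not taken as pairs. A part shared by same-numbered sets of 30 and 60 min is not excluded, since grouping these 4 sets by number gave 229 regions with an unadjusted p under 0.05 and 4100 loci, against 40 and 2342 in the crossed grouping and 629 and 5107 in the true one. Of 4502 regions, 229 is about the share that a threshold of 0.05 passes without any difference, and 40 is below it. The 229 alone thus does not show a shared part.

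The site lists held 26171, 23898, 23558 sites in the higher-scoring part, by construction, and 37825 to 41245, 30786 to 40991, 34054 to 38765 without 1 replicate number. Overlap of 0-min sites at 30 min, 0-min sites at 60 min and 30-min sites at 60 min was 62.3, 55.1, 66.1% when 50% of the width had to be shared, 85.1, 79.9, 89.2% for the higher-scoring part, 61.6, 55.5, 68% without the densest regions and 51.6 to 66.1, 50.7 to 57.5, 65 to 67.6% without 1 replicate number. Thinning gave 63% for 0-min sites at 30 min. Agreement within minus between times was 44.2 points for dsRNase and 12.7 for ssRNase in the higher-scoring part. Regions with at least 2 sites numbered 8293, 7454, 7022, and regions 4-fold and 100 nt apart 952 more and 338 less, 1044 more and 773 less, 169 more and 358 less, at 0, 30 and 60 min and in the order of comparisons above.

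With 1 set left out, so that 1 call rather than 2 decides, dsRNase loci gained and lost numbered 5950 to 12793 and 6479 to 13434, 7687 to 11864 and 7577 to 14085, 4248 to 7704 and 3697 to 10614, and ssRNase loci 2552 to 6979 and 562 to 2369, 1022 to 2157 and 1404 to 4210, 242 to 815 and 2576 to 7063. In the higher-scoring part dsRNase losses were 7974, 9171, 5200, and gains from 30 to 60 min 5229.

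In the same order of comparisons, regions whose change differed between the RNases numbered 2, 27 and 1, against 7, 43 and 6 with a prior of 0.25 calls and 38, 21 and 0 with a prior of 1 call, so the number depends on the prior. Regions gained at both times numbered 531 and 513, against 668, and regions lost at both times 22 and 15, against 71, when each comparison had 1 of the 0-min sets. These alternatives were chosen after seeing the data.

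The change of the chromosome 8 region at 11648692 from 30 to 60 min, close to 0 and not past the test, turned positive at 0.11 with scaling by all calls, 0.14 without scaling, 0.36 with both RNases, 0.77 with ssRNase alone, 0.29 with a 200 nt gap, 0.11 with the strand ignored (log2), and ranged from -0.56 to 0.46 with 1 set left out. For the chromosome 26 region at 3750692, 30 against 0 min, thinning gave 0.015, and for the chromosome 20 region at 15073149, 60 against 30 min, ssRNase alone gave 0.39. The ssRNase calls at 15073149 were 3 and 7 at 30 min and 3 and 4 at 60 min. They did not rise before scaling by the calls per set, so this reversal came from the scaling. The cause of the other reversals was not tested.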

Other observations

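The tests of chromosome shares in this part were chosen after the data had been seen, and what would count for or against the explanations of chromosome shifts and of neighbouring regions was written before those were tested.

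The share of dsRNase calls shifted between chromosomes. From 0 to 60 min chromosome 12 went from 4.16 to 3.50% of calls (log2 -0.25 ± 0.03 SE, limma adjusted p = 0.00128 over 27 chromosomes) and chromosome 7 from 4.16 to 3.63%, while chromosome 8 went from 2.90 to 3.35%, chromosome 10 from 3.51 to 4.02% and chromosome 22 from 2.55 to 2.92%. In the ssRNase sets chromosome 22 went from 2.87 to 4.10% (log2 0.51 ± 0.07, adjusted p = 0.000669) and chromosome 10 from 3.45 to 4.33%, and chromosome 12 from 3.73 to 2.98%. Chromosomes 7 (limma adjusted p = 0.129) and 8 (0.0614) did not pass there. Chromosomes 9, 11, 15 and 18 passed with ssRNase but not with dsRNase. Whether many separate changed regions add up to these shifts stays open. Of the 11 chromosomes past the test at 60 against 0 min, 2 (20 and 26) were past it without the 1301 regions that changed in any comparison. Without 1301 random other regions of like call number, 7 to 14 chromosomes were past it (mean 10.65, 20 draws). The condition written beforehand for this explanation was thus met. But regions picked because they changed reduce such shifts when left out, so these counts decide nothing. The fold of chromosome 12 went from -0.25 ± 0.03 to -0.06 ± 0.04 and that of chromosome 22 from 0.19 ± 0.05 to -0.05 ± 0.05, while chromosome 14 kept its fold (-0.11 ± 0.02 and -0.11 ± 0.04) but with the larger error did not pass. The folds of the 2 that stayed past the test grew, from 0.18 ± 0.05 to 0.25 ± 0.05 on chromosome 20 and from 0.14 ± 0.03 to 0.23 ± 0.04 on chromosome 26.

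Whether regions gain sites together with their neighbours was tested as a hypothesis. Among 160 neighbouring tested pairs on opposite strands within 5000 nt, both regions had gained at 60 min in 11, against a mean of 4.99 and a highest value of 16 in 1000 permutations (one-sided permutation p = 0.013). The bar set in advance, more than in every permutation, was not met. On the same strand 96 of 767 pairs had both gained, against a mean of 24.2 and a highest value of 41 (permutation p = 0.001, the smallest these permutations can give). Such pairs may be parts of 1 transcript divided by a gap of over 500 nt, as the 11 pairs on opposite strands cannot be. The number of gained regions may thus be above the number of gained transcripts, which was not tested.

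Some of the highest scores of the authors' lists recur at the same places. The top site at 0 min (chromosome 20, 228275 to 229598, minus strand, score 7411.97) ranked 9 at 30 min, as a shorter site, and 2 at 60 min. A site on chromosome 26 (1833 to 3190, minus strand, score 6584.87) ranked 2 at 0 min and 1 at 30 min, and a site over the same stretch ranked 1 at 60 min. Scaffolds 1078, 1097 and 1176 each held a site among the top 10 of all lists, 120 nt wide at 0 min, 93 nt at 30 min and 59 nt at 60 min. Scaffold 79 held 3 sites of 296 nt at 0 min with scores of 5001.2, 4688.52 and 4684.88, of which 1, at 38116, was among the top 10 at 30 min and all 3 at 60 min. Others did not recur there, such as a chromosome 26 site at 2000749 seen among the top 10 at 0 min alone and a chromosome 20 site at 125018 at 30 min alone. What these sequences are was not identified here.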
